A study of Nannochloropsis oceanica with 14 samples.

How the data were processed

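RNA of Nannochloropsis oceanica cultures was labelled with Cy3 and hybridised to Agilent one-colour arrays, 1 array per sample, 14 in all. Per the labels' protocols, cultures were axenic and started from a mixed pre-culture, RNA was extracted from cells collected on filters, and preparations with an RNA integrity number above 7 were used. The labels call the samples biological replicates. Times are those of the sample labels, 53 h and 70 h; the series design text gives slightly later times for these samples. Per the labels, 3 cultures were set up per condition, so arrays of different times can come from 1 culture, which the tests treat as independent.

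The scanner intensities were extracted with Agilent Feature Extraction 9.5.1.1, per the file headers. The processed intensity was background-subtracted and detrended within the array, with no scaling between arrays, and held surrogate values for spots near background, per the file headers. The submitters' processing notes name R 3.0.3 and limma 3.4, with steps not given in the sources used here. A value table deposited with the series held 1 column of intensity per sample, in whole numbers on a linear scale without background subtraction; its column medians lay between 608 and 612. Ranks in 11 of its 14 columns matched the median spot intensity of that sample's own scanner file best. In the other 3, all P-depleted 24 h, they matched another array of that group, so replicate numbers in that table differ from those of the scanner files while group comparisons are unaffected. The values and medians showed the scale and centring of the table's columns, and the rank matches showed their direction and array. It served as an alternative.

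Of 15744 spots, 536 control spots were left out. The 15208 remaining probes held 15098 distinct sequences of 60 bases, with 110 pairs of IDs sharing a sequence; these were averaged, a choice made after the files were seen. Processed intensities were divided by the 75th percentile of the array's non-control probes and taken to log2. Spots marked as outliers by the scanner software were left out, and saturated spots were kept. Probe sequences well above background on every array of at least 1 group were kept, which left 13853 and removed 1245, among them 2 with a group whose spots were all marked as outliers. Pairs of probes with identical sequence gave a technical SD of log2 intensity between 0.179 and 0.439 per array. No pair of arrays held identical signals in over 1% of probes (0 pairs).

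Differences were tested with limma 3.58.1 in R 4.3.3, with 6 group means fitted to all 14 arrays, 8 residual degrees of freedom and a prior of 2.32. Probes were called at a Benjamini-Hochberg adjusted p below 0.05 within each of 10 comparisons. Where a probe was not well above background on any array of a group, the fold is given as "at least N-fold". It is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Some probes not well above background measured higher than that lowest value, so the figure is not a strict lower limit. The limma step was tested on simulated data for 13853 probes, with 100 changed by 1 log2 unit and 100 by 2. The noise was normal and alike in all groups, with no outlying array, slide or culture. For 24 h against P-replete it recovered 41% of changes of 1 log2 unit and 84% of changes of 2, with 5 of 130 calls false. For 48 h against P-replete it recovered 24% and 71%, with 8 of 103 calls false. In the real data the share of changed probes, estimated from the p-values, was 20.1% at 24 h and 37.1% at 48 h. These rates therefore describe the simulated setting and not the real comparisons.

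The 14 arrays lay on 2 slides scanned separately. Slide 1 held 2 arrays of P-replete, 2 of P-depleted 24 h and both of 58 h, and slide 2 held the rest. Every comparison was repeated with the slide as a block and, where both groups were present, within each slide. Each later group lay on a single slide, so the slide term rests on the 24 h groups alone and is carried over to later times. The 53, 58 and 70 h arrays lay in the other row of the slides than the 24 h and 48 h arrays, so slide row and time cannot be told apart for those groups. Other alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, median centring, no filter on dim probes, a replicate block (4 calls between 53 h and 48 h), the groups compared alone, the deposited value table, a variance trend with robust estimation, a 2-fold minimum, the culture numeral in the file names as a block, and leaving out each array. These were chosen before the data were examined. Keeping probe IDs separate, leaving out P-depleted 24 h replicate 3 in comparisons without it, leaving out arrays from the correlations between times, and setting each time against different P-replete arrays were added after the data were seen.

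The rule for named probes was set before the data were examined: with no file pairing IDs with descriptions, the 2 called probes with the largest rise and the 2 with the largest fall in each comparison. No probe had a description (0 of 15208), and 0 IDs matched the reference table of organelle genes of strain IMET1. The 33 gene lists that had been fixed on phosphate nutrition, lipid metabolism, photosynthesis, translation, growth and stress therefore had 0 lists with a measured member, and no gene list was tested.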

Results

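Transcript levels were measured in Nannochloropsis oceanica strain CCMP1779, a unicellular marine alga that accumulates lipids. Axenic cultures were started from 1 mixed pre-culture in seawater medium with either 36.38 µM phosphate (P-replete) or 2.79 µM phosphate (P-depleted). P-replete cells were sampled at 24 h on 3 arrays. P-depleted cells were sampled at 24 h on 3 arrays and at 48, 53, 58 and 70 h on 2 arrays each, so that 14 one-colour arrays in 6 groups were compared. Each array carried 15208 probes of 60 bases against predicted transcripts of the alga, of which 83.9% to 98.0% were well above background on a given array. The 75th percentile of probe intensity lay between 1833 and 5107. After filtering, 13853 probe sequences were tested. No probe carried a gene name or description in the files, so probes are named by their array ID and sequence, and no function is assigned to them. Levels are log2 intensities relative to the 75th percentile of the same array, and a level is not comparable between probes. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.24 for 3 against 3 arrays, 0.27 for 2 against 3 and 0.30 for 2 against 2.

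P-replete and late P-depleted arrays lay at opposite ends of the main axis of variation. Component 1 held 38.7% of the variance, with P-replete arrays between -61.85 and -58.37, 48 h P-depleted arrays at 13.76 and 19.98, 58 h arrays at 36.89 and 48.9, and 70 h arrays at 47.03 and 48.62, so that 58 h and 70 h were not separated on it. Within P-replete, arrays correlated at 0.988 to 0.995 across probes, which are not independent replicates. Within P-depleted 24 h the range was 0.937 to 0.984. P-depleted 24 h replicate 3 stood apart, with a score of -111 on component 2 (24.9% of the variance) and the lowest 75th percentile of the 14 arrays, 1833. Because all groups share 1 estimate of the spread, this array also widened the error in comparisons that do not contain it.

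**Figure D1:**
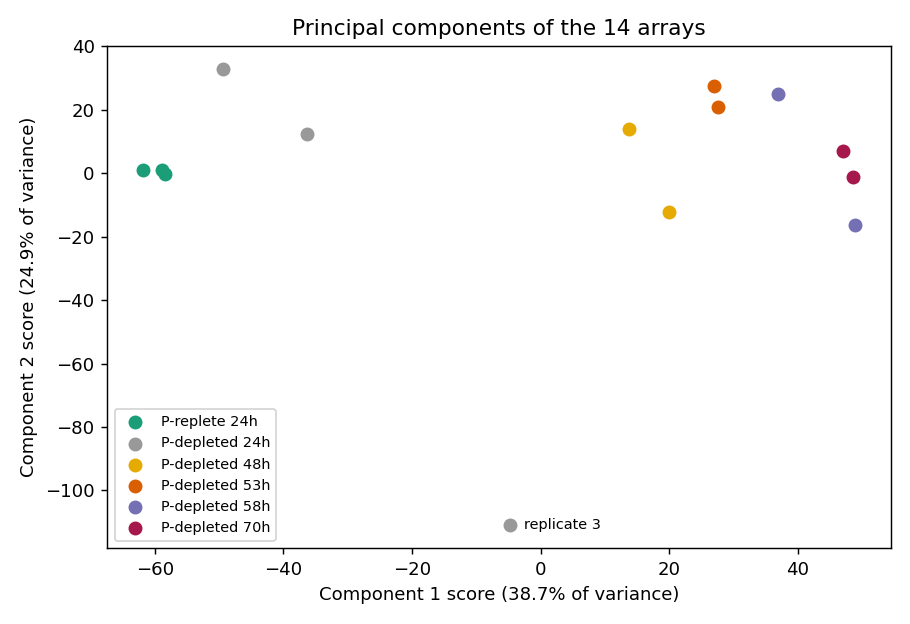
Scores of the 14 arrays on principal components 1 (horizontal axis, 38.7% of variance) and 2 (vertical axis, 24.9%), without units, with 1 point per array coloured by group. P-replete arrays lie at the left, the 58 h and 70 h P-depleted arrays at the right, and P-depleted 24 h replicate 3 lies apart at -111 on component 2.

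The comparison at 24 h was the one in which phosphate alone differed between groups sampled at the same time. At 24 h, 75 probes were higher and 26 lower in P-depleted than in P-replete cells, out of 13853 tested with limma at a Benjamini-Hochberg adjusted p below 0.05. Probe Nocean05539 (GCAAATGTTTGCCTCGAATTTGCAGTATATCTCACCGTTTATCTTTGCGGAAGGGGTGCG) rose 58.7-fold, from -7.05 ± 0.77 (SD, n = 3) to -1.17 ± 0.40 (SD, n = 3), with a log2 fold change of 5.88 ± 0.34 (SE) and a limma adjusted p of 1.37e-05; 2 of the 3 P-replete arrays measured it well above background. Probe Nocean01427 (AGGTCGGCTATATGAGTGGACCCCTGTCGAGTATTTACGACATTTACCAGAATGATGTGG) rose 39.3-fold, from -5.16 ± 0.45 to 0.13 ± 0.68 (SD, n = 3 each), and its limma adjusted p was 6.72e-05. For Nocean01427 too, 1 of the 3 P-replete arrays was not well above background, and the later folds of both probes rest on these P-replete values. Probe Nocean09469 (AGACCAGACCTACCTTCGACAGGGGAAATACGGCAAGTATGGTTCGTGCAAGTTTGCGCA) was at least 5.02-fold lower and probe Nocean02571 (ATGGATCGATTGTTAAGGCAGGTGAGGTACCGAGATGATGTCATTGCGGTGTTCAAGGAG) at least 3.02-fold lower in P-depleted cells, where neither was well above background on any of the 3 arrays. Their limma adjusted p-values were 0.00418 and 0.0297; the call of Nocean02571 was lost in 12 of 19 alternative settings and that of Nocean09469 within each slide. Of the 75 higher probes, 24 changed at least 4-fold and 5 at least 16-fold. With the deposited value table, 111 were higher and 88 lower, and with normexp background correction 110 and 86.

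The arrays lay on 2 slides. The 24 h count was 101, 99 with the slide as a block, 35 within slide 1 and 38 within slide 2, where each group had 1 array, and 15 when limma was fitted to the 6 arrays of these groups alone. It fell to 67, 60 and 60 without P-replete replicates 1, 2 and 3, and rose to 198 and 174 without P-depleted replicates 2 and 3. The number of lower probes varied widely. It was 30 with the slide as a block, 3 within slide 1 and 2 in the 6 arrays alone. Without P-replete replicates 1, 2 and 3 it was 14, 6 and 7, and without P-depleted replicates 1, 2 and 3 it was 47, 83 and 65. At an unadjusted limma p below 0.05, 662 probes were higher and 1097 lower.

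Later samples of the P-depleted cultures addressed how the response developed over time. At 48 h, by which time the response was wider, 1252 probes were higher and 1408 lower than in P-replete cells at 24 h. From here on, time in culture differed together with phosphate, because P-replete cells were sampled at 24 h alone. Nocean05539 rose 202-fold (log2 7.66 ± 0.38 SE, limma adjusted p 1.73e-06) to 0.61 ± 0.17 (SD, n = 2), and Nocean01427 rose 188-fold (log2 7.55 ± 0.43 SE, limma adjusted p 3.13e-06) to 2.39 ± 0.13 (SD, n = 2). Probe Nocean04431 (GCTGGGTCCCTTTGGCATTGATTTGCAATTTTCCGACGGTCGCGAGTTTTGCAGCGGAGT) was 13.4-fold lower, at -3.77 ± 0.17 (SD, n = 2) against -0.03 ± 0.12 (SD, n = 3), with a limma adjusted p of 4.15e-06. Probe Nocean04473 (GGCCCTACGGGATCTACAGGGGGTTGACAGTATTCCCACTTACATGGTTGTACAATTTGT) was 10.5-fold lower, but its 48 h arrays differed widely (SD 2.76, n = 2), 1 of them measured it above background, and its call was lost in 7 of 18 alternative settings, with a log2 fold change of -1.44 without 48 h replicate 2. Large measured falls were fewer than large rises: 174 higher and 81 lower probes changed at least 4-fold, and 30 higher and 0 lower probes at least 16-fold. At least 2-fold changes numbered 659 higher and 748 lower. Measured falls are limited by background, and this was not separated from a true difference. With median centring 1196 probes were higher and 915 lower, and within slide 2 610 were higher and 465 lower, so that which direction had more probes at 48 h depended on the scaling and on the arrays used. The count of 2660 became 1675 with the slide as a block and 1075 within slide 2, where P-replete had 1 array. It was 1613 and 1380 without 48 h replicates 1 and 2, 1727 without P-replete replicate 2 and 4435 without P-depleted 24 h replicate 3.

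At 53 h, 1478 probes were higher and 1765 lower than in P-replete cells, and with median centring 1469 were higher and 1229 lower. Nocean01427 rose 232-fold (log2 7.86 ± 0.43 SE, limma adjusted p 1.77e-06). Probe Nocean09181 (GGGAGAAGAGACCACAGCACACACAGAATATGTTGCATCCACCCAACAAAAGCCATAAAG) rose 204-fold, from -2.97 ± 0.34 (SD, n = 3) to 4.70 ± 0.41 (SD, n = 2), with a limma adjusted p of 2.27e-07. Nocean04431 was 14.7-fold lower (limma adjusted p 2.51e-06), close to its 48 h level. Probe Nocean02114 (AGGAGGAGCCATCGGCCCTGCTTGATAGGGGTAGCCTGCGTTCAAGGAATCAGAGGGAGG) was at least 5.47-fold lower (limma adjusted p 0.000423) and was not well above background on either 53 h array. The count of 3243 was 2323 with the slide as a block and 1568 within slide 2, where 802 were higher and 766 lower. It was 1531 and 2061 without 53 h replicates 1 and 2, and 4968 without P-depleted 24 h replicate 3.

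At 58 h, 1614 probes were higher and 2641 lower than in P-replete cells. Probe Nocean09629 (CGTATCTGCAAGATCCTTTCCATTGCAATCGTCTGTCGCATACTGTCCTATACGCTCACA), whose sequence is carried by 1 further ID, rose 306-fold, to 3.26 ± 0.74 (SD, n = 2), with a limma adjusted p of 1.8e-07. Nocean01427 rose 286-fold (limma adjusted p 1.22e-06). Nocean09469 was at least 6.36-fold lower (limma adjusted p 2.14e-05), and probe Nocean01267 (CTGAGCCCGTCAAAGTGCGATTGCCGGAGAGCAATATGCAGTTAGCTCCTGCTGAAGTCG) was at least 10.3-fold lower (limma adjusted p 3.96e-06); neither was well above background at 58 h. The median log2 change of all 13853 probes was -0.21 at 58 h and -0.13 at 70 h, and under quantile normalization -0.045 and -0.0021, so changes at these times are relative to that shift. Of the dimmest 10% of probes, 28 were higher and 282 lower at 58 h, with a median log2 change of -0.68, against 0.12 at 53 h and -0.07 at 70 h. With the deposited value table the 58 h split was 2452 higher and 2633 lower. The 58 h count of 4255 was 3711 with the slide as a block and 3167 within slide 1, and it was 2677 and 2622 without 58 h replicates 1 and 2 and 6462 without P-depleted 24 h replicate 3.

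At 70 h, 1817 probes were higher and 2317 lower than in P-replete cells, and with median centring 1892 were higher and 1755 lower. Nocean09629 rose 394-fold (log2 8.62 ± 0.28 SE, limma adjusted p 8.41e-08) to 3.62 ± 0.11 (SD, n = 2), the largest change of any named probe, and Nocean01427 rose 198-fold (limma adjusted p 1.67e-06). Probe Nocean08939 (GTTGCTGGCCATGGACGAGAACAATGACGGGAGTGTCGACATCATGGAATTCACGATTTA) was 31.4-fold lower, at -5.34 ± 0.09 (SD, n = 2) against -0.37 ± 0.09 (SD, n = 3), with a limma adjusted p of 3.22e-06; 1 of the 2 arrays at 70 h measured it above background. Probe Nocean07992 (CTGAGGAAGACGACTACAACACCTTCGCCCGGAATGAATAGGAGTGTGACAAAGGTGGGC) was 29.5-fold lower, at -3.72 ± 0.05 (SD, n = 2) against 1.16 ± 0.10 (SD, n = 3), with a limma adjusted p of 1.2e-06. At least 16-fold changes numbered 46 higher and 4 lower. The count of 4134 was 3268 with the slide as a block and 2290 within slide 2. It was 2369 and 2258 without 70 h replicates 1 and 2, and 6210 without P-depleted 24 h replicate 3.

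**Figure D2:**
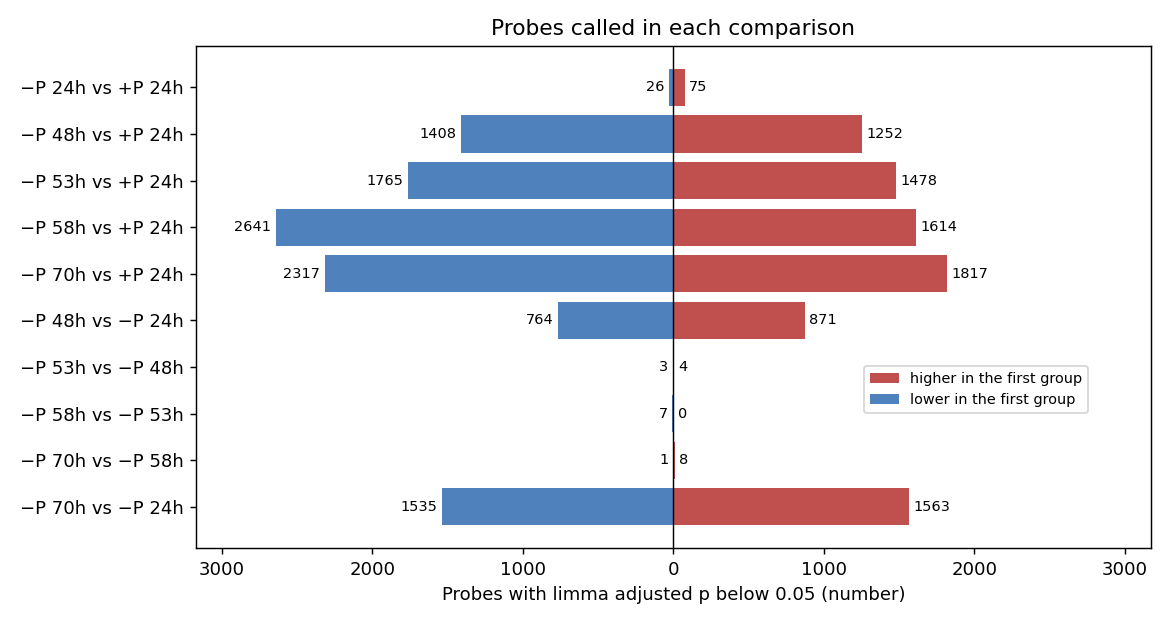
Number of probes called by limma (horizontal axis, adjusted p below 0.05) in each of the 10 comparisons (vertical axis), with bars to the right for probes higher and to the left for probes lower in the first group named. Counts with scaling to the 75th percentile reach 4255 for 58 h against P-replete and are 7 to 9 for the steps between 48 h and 70 h, which other scalings put at 0 to 495.

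All 75 probes that were higher at 24 h were also higher at 48 h, and 74, 74 and 70 of them at 53, 58 and 70 h. Their median log2 change from P-replete was 1.59 at 24 h, 2.81 at 48 h, 3.01 at 53 h, 3.00 at 58 h and 3.02 at 70 h. Of the 26 probes lower at 24 h, 19, 22, 24 and 22 were lower at 48, 53, 58 and 70 h, and 1, 1, 1 and 2 were higher. Independent lists would share 6.78 to 9.84 higher and 2.64 to 4.96 lower probes, without allowance for the P-replete arrays that the comparisons share. Over the 5 comparisons with P-replete, 5935 probes were called at least once, 837 were higher and 901 lower at all 4 later times, and 46 were higher at 1 time and lower at another.

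Changes from P-replete were correlated across probes between times, at 0.73 to 0.864 among 48, 53, 58 and 70 h and at 0.53 to 0.596 between 24 h and the later times. With no effect, the shared P-replete arrays gave simulated correlations of 0.16 to 0.398 over the 10 pairs. The simulated noise was independent between arrays, so it held no slide, slide row or culture in common between times. The covariance between 58 h and 70 h was 0.749 against a simulated 0.0259, and between 24 h and 48 h it was 0.19 against 0.0256. Between 58 h and 70 h, 1347 probes were higher and 1757 lower at both times, where independent lists would share 212 and 442. When each time was set against different P-replete arrays, 1 for one time and the others for the other time, the correlations were 0.665 to 0.799 among the later times and 0.42 to 0.496 with 24 h, as means over the 6 choices of arrays. The counts of shared probes were not recomputed in this way. This split does not allow for a slide, slide row or culture in common between times either. The highest correlation, 0.864, was between 53 h and 70 h, both in row 2 of slide 2. The lowest among the later times, 0.73, was between 48 h and 58 h, which differ in slide and row. Between 58 h and 70 h, on different slides, it was 0.849.

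Among P-depleted cells the step with the most calls, and the longest in time, was from 24 h to 48 h, with 871 probes higher and 764 lower. Fits to each pair of groups alone did not keep this order. They called 0 probes by limma at every step, with 1762, 2041, 2877 and 2278 at an unadjusted p below 0.05. Nocean09629 rose 27.9-fold (limma adjusted p 9.43e-05), from -3.21 ± 0.29 (SD, n = 3) to 1.59 ± 0.005 (SD, n = 2). Probe Nocean02456 (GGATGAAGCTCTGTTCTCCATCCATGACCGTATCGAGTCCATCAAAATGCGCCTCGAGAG) was at least 8.97-fold higher at 48 h (limma adjusted p 0.00153), and was not well above background on the 3 arrays at 24 h. Nocean04431 was 7.14-fold lower (limma adjusted p 0.000206), and probe Nocean05458 (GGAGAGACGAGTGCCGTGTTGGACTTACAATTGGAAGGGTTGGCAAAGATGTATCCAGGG) was 9.19-fold lower (limma adjusted p 0.01), with 1 of the 2 arrays at 48 h above background and a log2 fold change that moved from -3.20 to -2.58 and was no longer called without 48 h replicate 2. The calls of Nocean09629, Nocean02456, Nocean05458 and Nocean04431 were lost in 1, 2, 2 and 1 of 18 alternative settings. Of the 75 probes higher at 24 h, 60 rose further and 1 fell. The count of 1635 was 636 with the slide as a block and 159 within slide 2, where the 24 h group had 1 array, and 0 when limma was fitted to the 5 arrays of these groups alone (1762 at an unadjusted p below 0.05). It was 884 (345 higher and 539 lower) and 576 (284 and 292) without 48 h replicates 1 and 2, 3328 (1454 and 1874) without 24 h replicate 3, and 540 higher and 651 lower with the culture numeral as a block, so which direction had more probes was not stable.

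Between 48 h and 53 h, 4 probes were higher and 3 lower at 53 h, a count that depended on the scaling. Normexp background correction called 189 higher and 306 lower, and 174 were higher and 315 lower with the deposited value table. Probe Nocean01560 (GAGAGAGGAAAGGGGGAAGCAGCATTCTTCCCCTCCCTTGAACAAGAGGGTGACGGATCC) rose 71.5-fold, from -4.22 ± 0.23 to 1.94 ± 0.60 (SD, n = 2 each), with a limma adjusted p of 0.00885. At 70 h it measured -2.75 ± 1.44 (SD, n = 2), and the difference between 70 h and 58 h did not pass (limma adjusted p 0.125). Probe Nocean15042 (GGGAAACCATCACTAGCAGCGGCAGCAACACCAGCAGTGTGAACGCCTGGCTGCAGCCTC) was low at 48 h alone: it was 6.87-fold lower at 48 h than at 24 h (limma adjusted p 0.000206) and 8.89-fold higher at 53 h than at 48 h (limma adjusted p 0.00121). Probes Nocean04447 (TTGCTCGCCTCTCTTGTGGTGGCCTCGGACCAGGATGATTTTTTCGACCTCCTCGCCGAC) and Nocean07448 (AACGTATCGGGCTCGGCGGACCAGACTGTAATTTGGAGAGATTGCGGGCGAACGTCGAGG) were at least 5.07-fold and 3.98-fold lower at 53 h, with limma adjusted p-values of 0.00496 and 0.0455; the calls of Nocean01560, Nocean15042, Nocean04447 and Nocean07448 were lost in 4, 1, 3 and 9 of 18 alternative settings. Without 53 h replicate 1 neither Nocean01560 nor Nocean04447 was called (log2 changes of 5.74 and -3.91), nor was Nocean01560 without 48 h replicate 2 (6.32). The count of 7 was 4 with the slide as a block and within slide 2. It was 119 and 4 without 48 h replicates 1 and 2, 1 and 21 without 53 h replicates 1 and 2, and 187 without P-depleted 24 h replicate 3.

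Between 53 h and 58 h, 0 probes were higher and 7 lower at 58 h by limma, with 676 higher and 1690 lower at an unadjusted p below 0.05. Median centring called 3 higher and 183 lower, whereas limma called 0 with normexp, with the deposited value table and with the culture numeral as a block (2088, 2075 and 2458 at an unadjusted p below 0.05). Probes Nocean01726 (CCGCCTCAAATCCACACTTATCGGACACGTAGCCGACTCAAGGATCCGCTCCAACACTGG) and Nocean05168 (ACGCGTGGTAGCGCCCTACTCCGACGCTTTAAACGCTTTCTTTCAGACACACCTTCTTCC) were at least 3.45-fold and 2.48-fold lower (limma adjusted p 0.000406 and 0.0184), and neither was well above background at 58 h; Nocean05168 was above it on 1 of the 2 arrays at 53 h. Their calls were lost in 4 and 10 of 17 alternative settings. All 7 probes were dim, with a median brightness percentile of 3.29. Nocean01726 was called in the fit with the slide as a block, where the count was 1. The 53 h and 58 h arrays lay on different slides, so no value within a slide exists. By the culture numerals, 58 h replicate 2 also came from another culture than both 53 h arrays. The count was 1 without 53 h replicate 1, 18 and 2 without 58 h replicates 1 and 2, and 1006 without P-depleted 24 h replicate 3.

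Between 58 h and 70 h, 8 probes were higher and 1 lower at 70 h. Median centring called 79 higher and 0 lower, normexp and the deposited value table each 1 higher and 1 lower, and limma with the culture numeral as a block 0 (2752 at an unadjusted p below 0.05). Probe Nocean01311 (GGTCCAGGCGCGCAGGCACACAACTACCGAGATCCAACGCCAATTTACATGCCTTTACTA) was at least 3.09-fold higher (limma adjusted p 0.0248) and Nocean01726 at least 3.3-fold higher (limma adjusted p 0.000492). Probe Nocean07522 (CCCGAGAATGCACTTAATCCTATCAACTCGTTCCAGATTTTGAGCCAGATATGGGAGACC) was 2.09-fold lower at 70 h (limma adjusted p 0.0496). It was also 8.54-fold lower at 70 h than in P-replete cells (limma adjusted p 4.45e-07). The calls of Nocean01311, Nocean01726 and Nocean07522 were lost in 12, 4 and 11 of 17 alternative settings. The count of 9 was 1 with the slide as a block, and the groups lay on different slides and, by the culture numerals, differed in a culture. It was 25 and 2 without 58 h replicates 1 and 2, 1 without 70 h replicate 2, 9 without 70 h replicate 1 (1 higher and 8 lower), and 176 without P-depleted 24 h replicate 3.

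Over the whole P-depleted course, from 24 h to 70 h, 1563 probes rose and 1535 fell. Nocean09629 rose 114-fold (limma adjusted p 1.34e-06). Probe Nocean02734 (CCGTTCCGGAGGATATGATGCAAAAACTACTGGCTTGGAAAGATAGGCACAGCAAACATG) rose 92.1-fold, from -6.64 ± 0.31 (SD, n = 3) to -0.12 ± 0.07 (SD, n = 2), with a limma adjusted p of 3.55e-05; 2 of the 3 arrays at 24 h measured it above background. Nocean08939 was 23.5-fold lower (limma adjusted p 1.97e-05) and Nocean07992 22.1-fold lower (limma adjusted p 7.15e-06). The count of 3098 was 2104 with the slide as a block, 1227 within slide 2 and 370 when limma was fitted to these groups alone. It was 1592 and 1366 without 70 h replicates 1 and 2. Without 24 h replicate 3 it was 5483, with 2211 higher and 3272 lower, and with the culture numeral as a block 1374 were higher and 1858 lower.

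**Figure D3:**
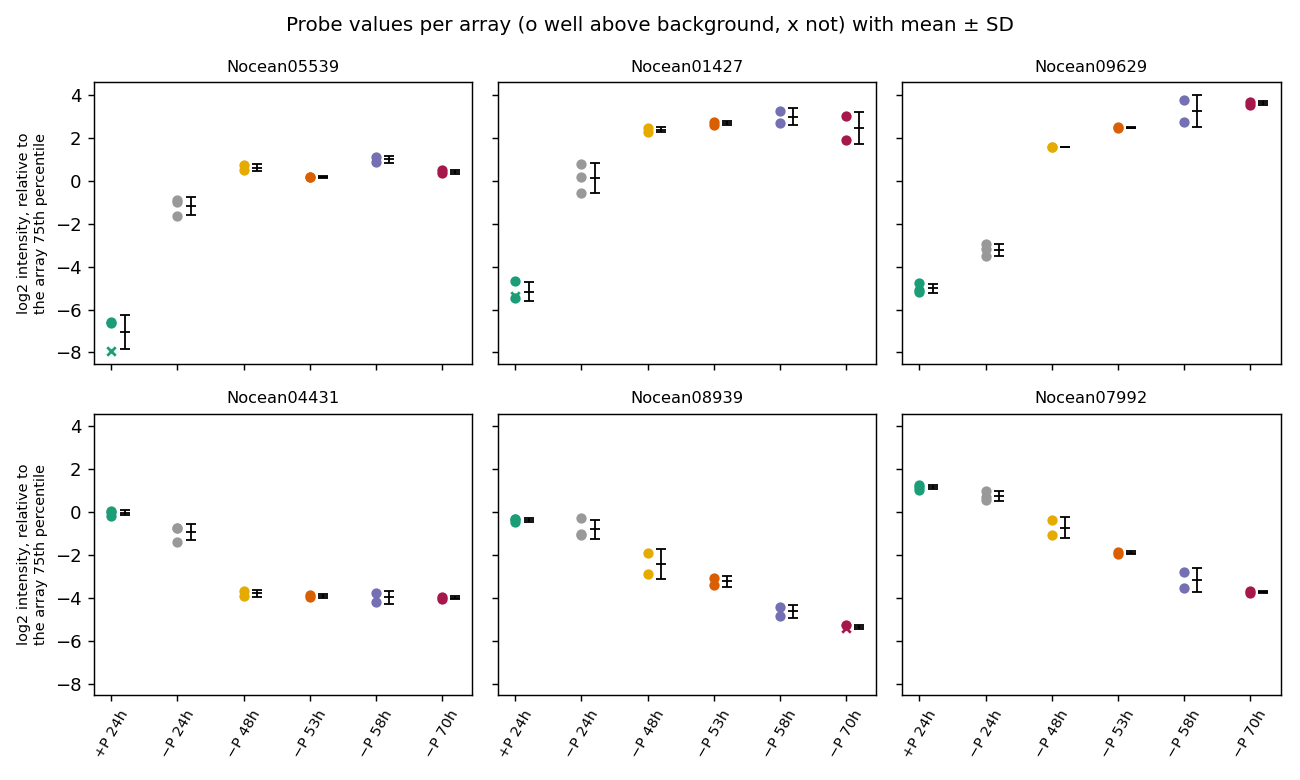
Log2 intensity relative to the array's 75th percentile (vertical axis) in the 6 groups (horizontal axis) for 6 named probes, with 1 point per array, crosses for arrays not well above background, and black marks for the group mean ± SD (n = 3 at 24 h, n = 2 later). Nocean05539, Nocean01427 and Nocean09629 lie higher and Nocean04431, Nocean08939 and Nocean07992 lower in P-depleted cells at 48 to 70 h than in P-replete cells.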

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

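All tests on P-depleted 24 h replicate 3, the test of the 58 h probes with the slide as a block the comparison with other dim probes and that with the dimmest 10% were chosen after the results were seen.

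Whether changes from P-replete differed between P-depleted times is the same limma test as the comparisons between those times, since the P-replete mean cancels. The calls were 1635 between 48 h and 24 h, 7 between 53 h and 48 h, 7 between 58 h and 53 h, 9 between 70 h and 58 h, and 3098 between 70 h and 24 h. Over the alternative settings other than leaving out arrays they ranged over 0 to 2311, 0 to 495, 0 to 186, 0 to 79 and 370 to 4328. The count of 101 probes at 24 h was set against the other splits of the 6 arrays: 1 of 10 splits, the real one, gave as many, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.

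P-depleted 24 h replicate 3 stood apart from replicates 1 and 2. Weak signal of dim probes is argued against as the whole account, because in the brightest 10% of probes its deviation was still 1.78 times that of equal noise (95% bootstrap interval over probes 1.63 to 1.97), although its mean deviation ran from -1.29 in the dimmest 10% to 0.13 in the brightest. An effect of slide 1 is also argued against, since its difference from replicate 1 correlated at 0.0321 across probes with the slide difference in P-replete. A culture further along in phosphate depletion stays open: in the brighter part of the probes the deviation correlated at 0.118 with later minus P-replete, between the bounds set, and replicate 1 minus replicate 2 gave 0.195. RNA quality per sample was not tested, and its deviation from the group mean correlated at 0.462 across probes with that of the 58 h array whose file name carries the same culture numeral (and so at -0.462 with the other 58 h array).

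The 7 probes lower at 58 h than at 53 h fell by a median of 2.75 on the log2 scale, and 6 of them were called higher again at 70 h. Both steps use the same 2 arrays at 58 h, so the rise is not separate evidence of a dip. The median slide difference of the 7 probes was -0.091 within P-replete and -0.452 within P-depleted 24 h. This argues against a slide effect of that size in slide row 1, where all arrays of these 2 groups lay. The 58 h arrays were the only ones in row 2 of slide 1, so an effect of that position cannot be told apart from 58 h. Background handling stays open: normexp left 15.8% of the difference, which met the bound set in advance for background handling as the cause. However, normexp also left 24.9% in 176 other dim probes with falls of that size. Those were called lower at 58 h against P-replete on the same 58 h arrays, so they may share an artifact. The dimmest 10% of all probes had a median change from P-replete of 0.12 at 53 h, -0.68 at 58 h and -0.07 at 70 h. The test could therefore not separate a real fall from an artifact. A change in the cultures at 58 h stays open too, since 1 of the 7 probes was still called with the slide as a block, where the median change was -2.35, while 0 probes were called by limma with the culture numeral of the file names as a block (2458 at an unadjusted p below 0.05). By the culture numerals, 58 h replicate 2 shared a culture with 24 h replicate 3 but with no array at 48, 53 or 70 h. The steps into and out of 58 h therefore also changed a culture. These explanations cannot be told apart with 2 arrays per time near background.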

How the results depend on the processing

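The tests added after the data were seen were probe IDs kept separate, leaving out P-depleted 24 h replicate 3 where it is not compared, leaving out arrays from the correlations between times, and setting each time against different P-replete arrays. Over 37 named results, 580 of 665 alternative values kept their direction and call, 85 lost the call and 0 reversed. The named probes were picked as the largest called changes in the same arrays, so reversals were unlikely from the start. These numbers do not measure how stable the other called probes are. The mean correlation between times (0.708) stayed within 0.673 to 0.717 leaving out single arrays, and was 0.751 with normexp, 0.687 without the filter and 0.627 with P-replete arrays not shared. Keeping IDs separate moved no count by over 1.5 times. Except where the construction shows it, the cause was not tested.

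The normexp setting called 196 probes at 24 h, 495 for 53 h against 48 h, 0 for 58 h against 53 h (limma, 2088 at an unadjusted p below 0.05) and 2 for 70 h against 58 h. The deposited table called 199, 489, 0 (limma, 2075 unadjusted) and 2. Quantile normalization called 36 for 53 h against 48 h and 3 for 58 h against 53 h. Median centring called 11 for 53 h against 48 h, 186 for 58 h against 53 h and 79 for 70 h against 58 h. No filter gave 3 for 53 h against 48 h, where more probes were tested. A variance trend with robust estimation gave 39, 1 and 3 for the steps from 48 to 53, 53 to 58 and 58 to 70 h.

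Scaling also moved the share of called probes that were higher. At 24 h it was 74.3%, and 56.1% with normexp and 55.8% with the deposited table. At 58 h against P-replete it was 37.9%, and 48.2% with the deposited table, 47.6% with normexp, 47.5% with quantile normalization and 38.1% with median centring. For 53 h against 48 h it was 57.1%, and 38.2%, 72.7% and 35.6% with normexp, median centring and the deposited table. For 58 h against 53 h it was 0%, and 33.3% with quantile normalization. For 70 h against 58 h it was 88.9%, and 50%, 75%, 100% and 50% with normexp, quantile, median centring and the deposited table. Median centring turned the majority at 48, 53 and 70 h against P-replete, with 56.7%, 54.4% and 51.9% higher where 47.1%, 45.6% and 44% were. Within slide 2 the majority also turned at 48 h (56.7%) and 53 h (51.1%). Median centring moved the median change of all probes from -0.10 to 0.02 at 48 h and from -0.00517 to 0.10 at 53 h, and quantile normalization from -0.11 to 0.00846 for 58 h against 53 h.

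The slide as a block gave 1675 for 48 h against P-replete, 636 for 48 h against 24 h, and 4, 1 and 1 for the later steps. The slide itself called 0 probes (limma, 873 at an unadjusted p below 0.05). That term was estimated from the 24 h groups alone, with P-depleted 24 h replicate 3 on slide 1. It does not show whether the slide affected the later groups, and the block counts for later times rest on it. Within slide 1 the 24 h count was 35. Within slide 2 it was 38, with 1075, 1568 and 2290 for 48, 53 and 70 h against P-replete, 159 for 48 h against 24 h, 4 for 53 h against 48 h and 1227 for 70 h against 24 h, all with fewer arrays.

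Fitting the compared groups alone gave 15 at 24 h, 4415, 5747 and 7215 at 48, 53 and 70 h against P-replete, and 370 for 70 h against 24 h. It gave 0 for 48 h against 24 h and for each later step (limma, 1762, 2041, 2877 and 2278 unadjusted). These fits lack the spread of the other groups. A 2-fold minimum gave 1407, 1755, 2498 and 2399 at 48, 53, 58 and 70 h, 818 for 48 h against 24 h and 1639 for 70 h against 24 h. The culture numeral as a block gave 2, 0 and 0 for the later steps (limma, 2458 and 2752 unadjusted for the zeros).

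A replicate block gave 4, 12 and 2 for the later steps and moved no other count by over 1.5 times. Whether the numbers pair the samples was not settled. Of 31 same-numbered pairs, 8 deviated together at above 0.1 (range -0.485 to 0.282). Among pairs with the same culture numeral, 5 of 17 did so (range -0.282 to 0.485). Of 14 arrays, 9 correlated best with their own title number. These counts were not set against those of unmatched pairs. In a group of 2 arrays the 2 deviations also mirror each other.

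Leaving out single arrays gave 60 to 198 at 24 h, and against P-replete 1380 to 4435 at 48 h, 1531 to 4968 at 53 h, 2622 to 6462 at 58 h and 2258 to 6210 at 70 h. It gave 576 to 3328 for 48 h against 24 h, 1 to 187 for 53 h against 48 h, 1 to 1006 for 58 h against 53 h, 1 to 176 for 70 h against 58 h and 1366 to 5483 for 70 h against 24 h. The highest value came without P-depleted 24 h replicate 3 in each but the 24 h comparison (198 without replicate 2). A lone remaining array is assumed to vary like the other groups. The brightest-probe alternative was not run, since each ID has 1 probe, nor were the gene list alternatives, since no list had members. Signal over background limits the dim probes.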

Other observations

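The test of bright probes at 53 h was chosen after the result was seen, as was the reading that quantile normalization removes such a shift by construction.

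Some transcripts crossed the background level. At 70 h, 40 probes were well above background on both arrays and on 0 of the 3 P-replete arrays, and 27 of these were called higher. In the other direction 172 probes at 70 h were well above background on the 3 P-replete arrays and on neither array of the group, of which 75 were called lower, 132 at 58 h, of which 101 were called lower, and 230 at 53 h, of which 67 were called lower. Upward crossings numbered 2 at 24 h, 12 at 48 h, 18 at 53 h and 25 at 58 h. Downward crossings numbered 6 at 24 h and 4 at 48 h, where upward ones were more frequent. The share of probes above background differed between arrays, from 83.9% to 98.0%, so these numbers also depend on each array's background.

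The transcripts with the strongest signal shifted downwards late in the course. Of the 139 brightest probes (the top 1% by mean over the 14 arrays), 12 were higher and 59 lower at 58 h, and 11 higher and 56 lower at 70 h, against P-replete. The balance differed from that of the other probes at 70 h (Fisher's exact test, two-sided, p 2.42e-06, adjusted p 6.6e-06 over 30 tests). Among these tests the dimmest 10% at 58 h differed most, with 28 higher and 282 lower (adjusted p 2.6e-31). Such p-values overstate the evidence, since probes are not independent. The scaling between arrays may account for it and stays open: the lowest ratio of falling to rising probes at 70 h was 1.52, under quantile normalization, which removes a shift of the whole class by construction, while median centring kept a ratio of 4.4. The ratio of 1.52 met the bound set in advance for scaling as the cause. Compression of bright signals on arrays with a high yield is a candidate explanation, since at 53 h, with 75th percentiles of 2305 and 3034, the median change was 0.205, against -0.53 at 70 h, with 5107 and 4099. At 48 h, with percentiles of 3201 and 2845 against 2677 to 3060 in P-replete, the median was -0.13. There 13 were higher and 24 lower (Fisher's exact test, adjusted p 0.212). Since the yields of these groups overlap, 48 h does not decide, and compression stays open too. This pattern is therefore not put forward as biological.

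Probes with consecutive ID numbers changed slightly alike. Over 12664 pairs the correlation across probes was 0.0324 at 24 h and 0.0529 at 48 h against P-replete, and its permutation p was 0.001 in each of 6 comparisons (adjusted p 0.001), the smallest that 1000 permutations can give. What the ID order stands for is not stated in the files.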
